A study of Homo sapiens with 12 samples.

How the data were processed

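Alternative splicing was measured by RNA sequencing in A549, an established human lung adenocarcinoma cell line. Per the labels' protocols, the cells stably expressed either wild-type MASCOT (WT), an endogenous circular RNA that binds the splicing factor hnRNP M, or a variant deficient in that binding (mhM). Cells of each kind were left untreated or given TGFβ, a cytokine that drives epithelial-mesenchymal transition (EMT), at 5 ng/ml for 72 h. Total RNA was depleted of ribosomal RNA and sequenced as paired-end reads of 150 bp. The 12 libraries formed 4 groups of 3 replicates, taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure at most the spread between these libraries, which may be technical.

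The authors deposited percent spliced in (PSI), a fraction from 0 to 1, with a value for each of 97203 splicing events in each of the 12 libraries and 0 missing values. Reads were aligned with STAR to the hg19 build, per the submitters' processing notes. The STAR version, the program that computed PSI, the gene annotation and any filter on read support are not given in the sources used here. The deposited fractions carry no read counts, so the depth behind each value is unknown and no interval that needs it was computed. A fraction of exactly 0 or 1 may rest on very few reads. The events fell into 7 types: 46675 skipped exons, 15452 alternative first exons, 10472 alternative 3' splice sites, 9894 alternative 5' splice sites, 6569 retained introns, 5507 alternative last exons and 2634 pairs of mutually exclusive exons.

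What PSI counts in each type was worked out from the values. Skipped-exon PSI was inclusion, with a median event mean of 0.952. For alternative splice sites and first and last exons, PSI was the share of the shorter junction: across events it followed the inclusion of a skipped exon whose inclusion uses that junction, with r from 0.926 to 0.977. For retained introns PSI was retention, with a median of 0.0784 where the intron was the main junction and 0.903 where it was a minor one. For mutually exclusive exons PSI was the share of the second-listed exon. Event coordinates are 1-based positions on hg19 and gene symbols are as deposited.

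Events with the same value in every library (2531) were removed, which left 94672 events of 13382 genes. Limma 3.58.1 in R 4.3.3 was fitted to PSI with 1 mean per group over all 12 libraries, an intensity-dependent variance prior (eBayes with a trend), two-sided tests and Benjamini-Hochberg adjustment over all events. The prior had 0.993 degrees of freedom. An event with no spread within any group takes its standard error from this prior alone, so its small p-value does not measure spread between libraries. An event was called when its adjusted p was under 0.05 and its difference in mean PSI was over 0.1. The contrasts were TGFβ in mhM cells, TGFβ in WT cells, their difference (the interaction), and WT against mhM without and with TGFβ. The study's own size rule, which has no test, counted events with a difference of group means over 0.1 in mhM and under 0.1 in WT. It was set beside the same rule with the constructs exchanged and beside all 400 reassignments of construct labels within each treatment (exact permutation test, two-sided). Events were also selected on 4 mhM libraries and measured again in the left-out mhM pair, over 9 choices.

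The gene lists, 15 in all, included genes with EMT-regulated exons, splicing regulators of EMT, SR proteins with TRA2 and SR kinases, the hnRNP family, the core spliceosome, the TGFβ and SMAD pathway, EMT transcription factors and markers, cell junctions and polarity, the actin cytoskeleton and focal adhesions, extracellular matrix and integrins, nonsense-mediated decay, DNA repair and cell cycle, mitochondrial respiration, and markers of fibroblasts, leukocytes and endothelial cells. Each was compared with 10000 random gene lists matched on the number of tested events per gene (permutation test). The groups, contrasts, lists, settings to vary and the rule for named events were fixed before the data were examined. Under that rule, each TGFβ contrast and the interaction names the 8 called events with the largest rise and the 8 with the largest fall, without overlap between libraries and with 1 event per gene; called events too few for that are followed by the smallest p, said not to be called. The rule adds the smallest p from each list and CD44, FGFR2, CTNND1, ENAH and HNRNPM. Each of these genes is followed in every contrast through 1 event, the one with its smallest p for TGFβ in mhM cells. Whether that event is the gene's EMT-regulated one was not checked. The contrasts between constructs name the 5 largest rises and falls and the same genes. Some of the events and lists so chosen are not reported here.

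After seeing the data, a TGFβ contrast averaged over both constructs was added, and the fits were repeated on smaller sets of events. Stable events were those with a mean PSI from 0.05 to 0.95 and a standard deviation over the 12 libraries under 0.1 (22681 events); that limit also leaves out events with large differences between groups. Other added sets had no library at 0 (67294 events), no events at 0 or 1 in every library, or 1 entry per distinct set of values. For stable events the share of a list's events with unadjusted p under 0.05 was compared with random lists, over 6 contrasts. Settings varied by plan were the logit of PSI with 0.01 added, a replicate block, only the groups compared, no size limit or 0.2, no variance trend, a PSI range of at least 0.05, and leaving out each library. The test of sequence around exons was not run, because it needs the hg19 genome sequence, which was not used here.

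The procedure was tested on simulated libraries drawn around each event's mean with its observed spread. With 100 stable events moved by 0.2 and 100 by 0.4 in the simulated mhM TGFβ group, limma over 89466 events found 20 and 74 of them and called 27 unchanged events. Over 22676 stable events it found 46 and 88 and called 9 unchanged events. Stable events were chosen here before any was moved, and the limit on the standard deviation was not applied again. That limit leaves out events with large differences. The counts for stable events therefore do not measure what a fit on observed stable events can find. In the simulated WT contrast, where nothing was moved, it called 32 events over all events and 0 over stable events. For the simulated interaction it found 11 and 39 over all events and called 55 unchanged events, and over stable events it found 27 and 78 and called 11. Under the size rule with no effect simulated, 47.0% of 12530 responsive events were under 0.1 in the other construct. With 5000 events moved in mhM only, that share was 59.1%. The list test on a simulated excess of hits among hnRNP genes gave p = 0.001 by permutation. Python 3.11.15, the R package data.table in version 1.17.8, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were also used.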

Results

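PSI values were compared among 4 groups of 3 A549 libraries: cells with the hnRNP M-binding-deficient MASCOT variant (mhM) or wild-type MASCOT (WT), each untreated or with TGFβ at 5 ng/ml for 72 h. The question, as the submitters state it, was how far the contact between MASCOT and hnRNP M shapes alternative splicing during EMT. Libraries were alike in their broad make-up. Mean PSI lay between 0.586 and 0.592, values of exactly 0 made up 14.8% to 16.5% and values of exactly 1 made up 21.4% to 23.4% of a library. The mean correlation of a library with the others, across events, ran from 0.875 in WT TGFβ replicate 3 to 0.887. Each WT TGFβ library correlated less with its own group (0.874 to 0.881) than with all others (0.875 to 0.887), unlike in the other groups. The median standard deviation (SD) within groups was 0.0280, and 23.2% of events had a within-group SD over 0.1. Values are group means ± SD with n = 3 throughout, the read depth behind them is unknown, and adjusted p-values are from limma. For events with no spread within any group, those p-values rest on the variance prior and not on observed spread. For all other events the spread was pooled over all 4 groups. It could come wholly from groups outside the contrast. This was so for PSMC5, RASSF8-AS1 and the KRT15 first exon with TGFβ in mhM cells, and for CTSB with TGFβ in WT cells.

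TGFβ in mhM cells defines the responsive events of the study, because this variant is deficient in hnRNP M binding. The alternative first exon of KRT15, a basal epithelial keratin, fell from 1 to 0 (chromosome 17, 39674713 to 39678587; adjusted p = 0.00011). TXNRD2, which encodes the mitochondrial thioredoxin reductase, raised the share of its shorter first-exon junction from 0.0442 ± 0.0053 to 0.154 ± 0.014 (chromosome 22, 19868240 to 19870848; adjusted p = 0.020). A 103-bp exon of PSD, a regulator of ARF GTPases, went from full inclusion in each untreated library to 0 in each library with TGFβ (chromosome 10, event 104174986 to 104176142; adjusted p = 1.4e-08).

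In all, 17 events of 16 genes were called, 7 higher and 10 lower with TGFβ. In simulated libraries the WT contrast, where nothing was moved, gave 32 calls, so a count of this size can arise without any response. Rises were also called at the PRSS36 5' splice site (0 to 1) and in first exons of TSGA10 (0 to 1), CRYZL1 (0 to 1), ZADH2 (0 to 0.889 ± 0.19) and HERC3 (0 to 0.166 ± 0.030). GTPBP2, next by p, was not called because its 3' splice site differed by 0.03. The falls included ends of PHF21B, SERGEF and AC017099.3, each from 1 to 0 in every library (adjusted p = 1.4e-08). PSMC5, a proteasome ATPase, used its shorter 3' splice site fully in untreated libraries and not with TGFβ (adjusted p = 0.046), RASSF8-AS1 went from 1 to 0 at its first exon (adjusted p = 0.0498), and STARD10, a lipid transfer protein, went from 0.917 ± 0.14 to 0. Alternative first exons made up 11 of the 17 calls (Fisher's exact test against all other types, adjusted p = 4.19e-05) and skipped exons 2 (adjusted p = 0.00889). Against only events with a library at 0, which are commoner among first exons (7949 of 14640) than among skipped exons (7507 of 45824), the same test gave adjusted p = 0.0195 for first exons and 0.295 for skipped exons. Of the called events, 7 were at 0 or 1 in all 12 libraries and 15 had at least 1 library at 0. Among the 67294 events with no library at 0 only TXNRD2 was called. TXNRD2 lost its call among stable events (adjusted p = 0.20) and with a PSI range of at least 0.05 (0.30), and STARD10 with the logit of PSI (0.10). PSMC5 and RASSF8-AS1 lost theirs without any 1 of the 6 libraries compared (adjusted p from 0.060 to 0.073 and from 0.058 to 0.088). Both had no spread within either mhM group, so that loss does not show a single library standing apart. Their calls were also lost without the variance trend (each 0.0544) and without events at 0 or 1 in every library (0.064 and 0.065). With 1 entry per distinct set of values they were lost too (0.0534 and 0.060).

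Genes with EMT-regulated exons had 0 calls by limma in mhM cells, also adjusted over the list alone, and 46 of 670 events at unadjusted p under 0.05. The other gene lists outside the actin cytoskeleton also had 0 calls by limma and 0 adjusted over the list alone. At unadjusted p under 0.05 there were 8 of 194 events for splicing regulators of EMT, 16 of 218 for SR proteins, 10 of 389 for the hnRNP family, 5 of 461 for the core spliceosome, 19 of 384 for the TGFβ and SMAD pathway and 7 of 208 for EMT transcription factors and markers. There were 17 of 333 for cell junctions, 52 of 867 for actin, 13 of 460 for extracellular matrix, 8 of 173 for nonsense-mediated decay, 41 of 738 for DNA repair, 7 of 421 for respiration and 2 of 50 for markers of other cell types. The smallest p in several lists fell on small differences: SEC31A, a COPII coat subunit, had an exon at 0.988 ± 0.0028 and 0.998 ± 0.0025 (adjusted p = 0.62), and PVRL2, the adhesion molecule nectin-2, a 3' splice site at 0.871 ± 0.016 and 0.938 ± 0.015 (adjusted p = 0.49). ENAH, an actin regulator, included its 111-bp exon at 0.884 ± 0.0030 and 0.849 ± 0.0088 (adjusted p = 0.97). HNRNPM itself included a 45-bp exon at 0.979 ± 0.0036 and 0.990 ± 0.0035 (chromosome 19, 8538548 to 8538592; adjusted p = 0.97). CTNND1, CD44 and FGFR2 also had adjusted p = 0.97, with PSI of 0.0259 ± 0.0054 and 0.0168 ± 0.0042 for an 87-bp exon, 0.974 ± 0.023 and 1 for a 5' splice site, and 1 and 0.652 ± 0.13 for a 78-bp exon. For these genes, ENAH and HNRNPM, the event shown had the gene's smallest p here. It need not be the gene's EMT-regulated event. Among stable events, a measure chosen after seeing the data, 27 of 243 events of genes with EMT-regulated exons (11.1%) and 21 of 171 of the actin list (12.3%) had unadjusted p under 0.05, against random-list medians of 5.05% and 4.97% (permutation p = 0.0086 and 0.0072, adjusted p = 0.0645 for each). The permutation p reached 0.128 without mhM TGFβ replicate 2 and 0.461 without mhM untreated replicate 1, respectively. Without 1 library the shares ran from 7.82% to 11.5% for EMT-regulated exons and from 5.85% to 9.94% for actin.

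**Figure D1:**
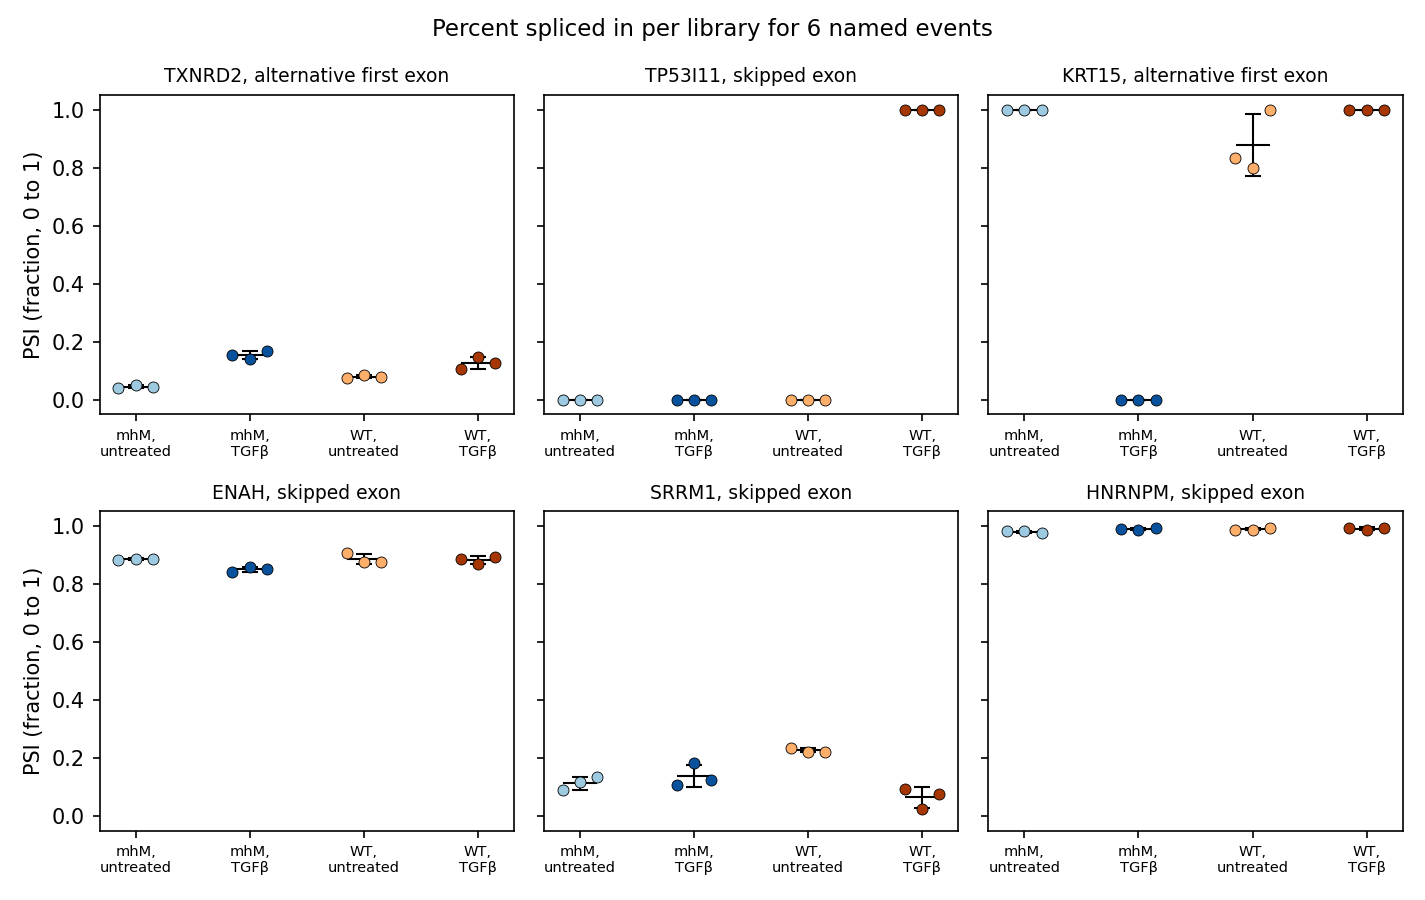
PSI (fraction from 0 to 1, vertical axis) in each library for 6 named events, by group on the horizontal axis; dots are libraries and black bars are the mean ± SD of 3. TP53I11 and KRT15 moved over nearly the whole range between groups, while ENAH, SRRM1 and HNRNPM moved by less than 0.2 and TXNRD2 rose from 0.0442 to 0.154 in mhM cells.

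TGFβ in WT cells asks the same of cells whose MASCOT binds hnRNP M. A 75-bp exon of TP53I11, a p53-induced gene, went from 0 in each untreated library to 1 in each library with TGFβ (chromosome 11, event 44960741 to 44972428; adjusted p = 1.4e-08). The shorter 5' splice site of CTSB, the lysosomal protease cathepsin B, also went from 0 to 1 (adjusted p = 0.037). Falls from 1 to 0 were called for 5' splice sites of CRB1, an apical polarity gene, and APBB2, and for an intron of FAM166A (each adjusted p = 1.4e-08). GOLGA8H, a member of a family of near-identical golgin copies in which reads can be shared, included a 69-bp exon at 1 without and 0.715 ± 0.049 with TGFβ (adjusted p = 0.040). SRRM1, a splicing coactivator, had a 143-bp exon at 0.226 ± 0.0068 and 0.065 ± 0.036, which did not pass (chromosome 1, event 24973699 to 24975350; adjusted p = 0.12).

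In all, 17 events of 13 genes were called in WT cells, 10 higher and 7 lower. Rises were also called in UNC5CL (0.111 ± 0.19 to 1), C2orf42 (0.133 ± 0.12 to 1), PRSS8, which encodes the membrane protease prostasin (0.133 ± 0.23 to 1), and CRYZL1 (0 to 0.867 ± 0.23). CCDC66 and CHD6 were next by p and not called, with differences of 0.04 and 0.02. Further falls were called in PRR13 (1 to 0) and SMARCA2, an ATPase of the SWI/SNF remodeller (0.917 ± 0.14 to 0.111 ± 0.19), and PPP1R13B followed uncalled with a difference of -0.03. No event type was called more often than the rest (5' splice sites had the smallest adjusted Fisher's exact p, 0.167). Of the 17 calls, 5 were at 0 or 1 in all 12 libraries and 16 had a library at 0; the other, GOLGA8H, was lost among events with no library at 0 (adjusted p = 0.089). Calls were lost without 1 library, with the highest adjusted p given here, for CTSB (any WT untreated, 0.065), CRYZL1 (any WT untreated or WT TGFβ replicate 1, 0.090), GOLGA8H (any WT untreated or WT TGFβ replicate 3, 0.072) and SMARCA2 (WT untreated replicates 1 or 3 or WT TGFβ replicates 2 or 3, 0.087). They were also lost with the logit of PSI for C2orf42 (0.18), SMARCA2 (0.19) and GOLGA8H (0.13), without the variance trend for SMARCA2 (0.071) and GOLGA8H (0.061), and without events at 0 or 1 in every library for SMARCA2 (0.0523).

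None of the 15 lists held a called gene in WT cells by limma, and every list had adjusted p = 1. Adjusted over the list alone, 4 events of SR proteins, 1 of the hnRNP family and 1 of the TGFβ and SMAD pathway passed. At unadjusted p under 0.05 there were 31 of 218 events of SR proteins, 25 of 389 of the hnRNP family, 30 of 384 of the TGFβ pathway, 36 of 670 of genes with EMT-regulated exons, 12 of 194 of splicing regulators of EMT and 16 of 461 of the core spliceosome. There were 17 of 208 for EMT transcription factors, 19 of 333 for junctions, 60 of 867 for actin, 25 of 460 for matrix, 6 of 173 for nonsense-mediated decay, 51 of 738 for DNA repair, 21 of 421 for respiration and 4 of 50 for markers of other cell types. HNRNPH3 included a 140-bp exon at 0.978 ± 0.0092 without and 0.864 ± 0.012 with TGFβ (adjusted p = 0.12). A first-exon event of TGIF1, a SMAD corepressor, read 0 and 1 (chromosome 18, 3448595 to 3456352, adjusted p = 0.13). Another TGIF1 first-exon event with the same outer coordinates read 1 in every WT library. PRPF6, a protein of the spliceosomal tri-snRNP, had 0.984 ± 0.0031 and 0.952 ± 0.0047 (adjusted p = 0.058), and SMG1, the kinase of nonsense-mediated decay, 0.988 ± 0.00057 and 0.933 ± 0.017 (adjusted p = 0.080). ENAH stood at 0.885 ± 0.018 and 0.882 ± 0.013 (adjusted p = 1) and HNRNPM at 0.988 ± 0.0039 and 0.990 ± 0.0050 (adjusted p = 0.99). CD44 had 0.989 ± 0.0093 and 1 (adjusted p = 0.91), FGFR2 0.667 ± 0.58 and 1 (adjusted p = 0.88) and CTNND1 0.0206 ± 0.0029 and 0.0188 ± 0.0048 (adjusted p = 1). Among stable events, a measure chosen after seeing the data, 16 of 78 SR protein events (20.5%) had unadjusted p under 0.05 with TGFβ in WT cells, against a random-list median of 6.90% (permutation p = 0.0018, adjusted p = 0.027). That share ranged from 15.4% to 32.1% without 1 library, and its p reached 0.059 without WT TGFβ replicate 3. Its adjusted p covers the 15 lists of this contrast alone, not the 6 contrasts tried. This contrast shares its WT untreated libraries with the comparison of WT and mhM without TGFβ.

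The study's own rule asks which responses in mhM cells are lost in WT cells, by size alone. The events named for it here were chosen after their values were seen. An 81-bp exon of MAP3K7, the TGFβ-activated kinase TAK1, had 0.409 ± 0.015 and 0.240 ± 0.045 in mhM cells and 0.298 ± 0.015 and 0.287 ± 0.083 in WT cells (chromosome 6, 91254271 to 91254351). The share of the shorter first-exon junction of TPM1, tropomyosin 1, was 0.486 ± 0.0033 and 0.272 ± 0.013 in mhM and 0.427 ± 0.015 and 0.378 ± 0.050 in WT. A 33-bp exon of CA12, a membrane carbonic anhydrase, also meets the rule with 0.889 ± 0.0030 and 0.763 ± 0.0085 in mhM and 0.885 ± 0.0092 and 0.788 ± 0.012 in WT; it was called in mhM cells (adjusted p = 0.028). That call was lost among stable events (adjusted p = 0.20), with the logit of PSI (0.39), with a PSI range of at least 0.05 (0.23) and among events with no library at 0 (0.58). It was also lost without events at 0 or 1 in every library (0.065), with 1 entry per distinct set of values (0.061) and without mhM untreated replicate 2 (0.0503). The interaction test did not pass for TPM1 or MAP3K7 (each adjusted p = 0.94 over stable events).

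By this rule, 13803 events responded in mhM cells (6641 higher and 7162 lower), and 6409 of them (46.4%) differed by less than 0.1 in WT cells. The series text states 9544 responsive events of which 4149 (43.5%) were attenuated; the filter behind the smaller number is not given in the sources used here. With the constructs exchanged, 14624 events responded in WT cells, and 7237 of them (49.5%) differed by less than 0.1 in mhM cells. Among the 7385 events over 0.1 in both, 3889 moved the same way. The forward share was 3.06 percentage points below the reverse share (-3.06; exact permutation p = 0.14, two-sided, 400 assignments), and over these assignments the forward share ran from 45.1% to 50.6% with a median of 47.7%. Without any 1 of the 6 mhM libraries the order turned, with 47.0% to 47.7% forward and 45.2% to 46.0% reverse, and without any 1 of the 6 WT libraries the shares were 42.2% to 43.6% and 49.5% to 51.8%. Both shares set aside the same events over 0.1 in both constructs, so their order follows which construct had more responsive events. Without 1 mhM library the mhM count was 14872 to 15146, above the 14624 of WT. The turn therefore does not bear on attenuation. The permutation test likewise compares in effect these counts, and not whether the same events responded less in WT cells. Skipped exons had 46.5% forward and 50.2% reverse, retained introns 49.2% and 56.1%, and alternative first exons 47.4% and 48.8%. Events responded least often among skipped exons in mhM (9.81%) and most often among alternative first exons (21.8%). Across all events the responses in mhM and in WT correlated with r = 0.0236, and across stable events with r = 0.0639; events are not independent replicates.

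**Figure D2:**
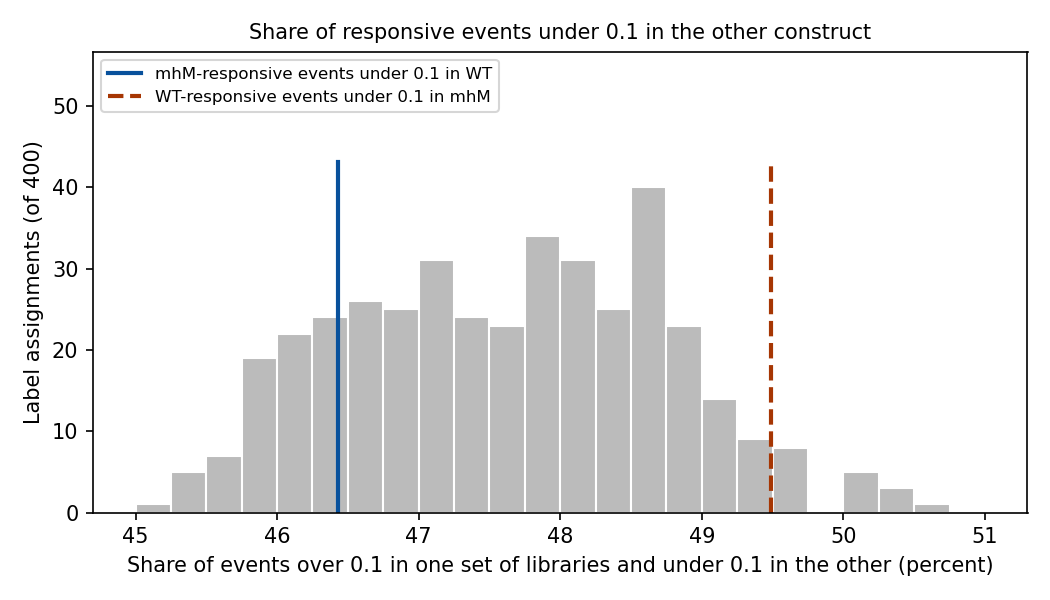
Share of events over 0.1 in one set of libraries and under 0.1 in the other (percent, horizontal axis) over all 400 assignments of construct labels within treatments (vertical axis, number of assignments). The solid line marks mhM-responsive events under 0.1 in WT (46.4%) and the dashed line the exchanged rule (49.5%), and both lie inside the range of the assignments.

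When events were chosen on 4 mhM libraries, their mean response of 0.305 was not kept in the left-out mhM pair. The signed response there was 0.00881 (range over 9 choices 0.00378 to 0.0115), against 0.00465 in WT pairs. In the left-out mhM pair 48.8% of the chosen events differed by less than 0.1, and in WT pairs 48.9%. For events with no library at 0 the chosen mean was 0.183 and the left-out mean 0.00247, against 0.00666 in WT pairs. For stable events these were 0.132 and 0.00496, against 0.00476 in WT pairs.

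The interaction tests directly whether the response to TGFβ differed between constructs. PRSS36 and HERC3 responded in mhM cells and not in WT cells, with differences of -1 and -0.17 (adjusted p = 1.7e-06 and 0.025). PRSS36 already stood at 1 in every WT untreated library, so it could not rise there. KRT15 moved from 1 to 0 in mhM cells and from 0.878 ± 0.11 to 1 in WT cells (difference of responses 1.12, adjusted p = 0.00052). TP53I11 responded in WT cells, by 1 (adjusted p = 1.6e-07). In all, 14 events of 12 genes were called, 8 higher and 6 lower, and they included PSD, PHF21B, SERGEF and AC017099.3 (each 1, after falls in mhM) and CRB1, APBB2 and FAM166A (each -1, after falls in WT). Events of PSD, PHF21B, SERGEF and AC017099.3 were at 0 in every WT library and could not fall there. Likewise those of CRB1, APBB2 and FAM166A were at 0 in every mhM library. ZADH2 was not called (difference -0.89, adjusted p = 0.076, but 0.0457 without mhM TGFβ replicate 2 and 5.4e-08 without replicate 3), nor were TTC28-AS1 and TMEM161A (each 0.04) or PPP1R13B (-0.03). Alternative first exons made up 6 of the 14 calls (Fisher's exact adjusted p = 0.0474) and skipped exons 2 (adjusted p = 0.0474). Against only events with a library at 0, neither passed (adjusted p = 0.585 and 0.647). Of the 14 events, 12 were at 0 or 1 in every library, and 0 were called by limma among events with no library at 0, of which 4.43% had unadjusted p under 0.05 (3868 events, 4.09%, in the full set). HERC3 lost its call with a PSI range of at least 0.05 (adjusted p = 0.11) and without events at 0 or 1 in every library (0.088).

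The gene lists outside the actin cytoskeleton had 0 called genes in the interaction by limma. Adjusted over the list alone, 1 event of the TGFβ and SMAD pathway passed, a TGIF1 first-exon event (difference 1.4). Over all events its limma adjusted p was 0.20, but 0.042 with the logit and 0.00037 without mhM TGFβ replicate 2. Unadjusted p was under 0.05 for 30 of 670 events of genes with EMT-regulated exons, 7 of 194 of splicing regulators of EMT, 19 of 218 of SR proteins, 13 of 389 of the hnRNP family, 15 of 461 of the core spliceosome and 23 of 384 of the TGFβ pathway. It was under 0.05 for 5 of 208 events of EMT transcription factors, 18 of 333 of junctions, 47 of 867 of actin, 17 of 460 of matrix, 7 of 173 of nonsense-mediated decay, 33 of 738 of DNA repair, 11 of 421 of respiration and 2 of 50 of markers of other cell types. EXOC7, an exocyst subunit with an EMT-regulated exon, had a 69-bp exon at 0.0705 ± 0.015 and 0.0443 ± 0.0061 in mhM and 0.0470 ± 0.0092 and 0.0835 ± 0.011 in WT (adjusted p = 0.51). The SRRM1 exon differed in response by -0.19 (adjusted p = 0.44). ENAH, CD44, FGFR2, CTNND1 and HNRNPM each had adjusted p = 0.90, with a difference in response of 0.03 for ENAH.

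Without TGFβ, WT and mhM cells were compared at rest. Each construct was carried by its own stably expressing cells, so other differences between these cells cannot be told apart from the construct. CRB1, APBB2 and FAM166A were at 1 in each WT library and 0 in each mhM library, and PSD, PHF21B, SERGEF and AC017099.3 the reverse (each adjusted p = 9e-09). For these events the calls here, with TGFβ and in the interaction all rest on the same untreated libraries that stood apart. PRSS36 was at 1 in WT and 0 in mhM (adjusted p = 9e-08), and PSMC5 at 0 in WT and 1 in mhM (adjusted p = 0.046). Of 22 stable introns of listed SR, TRA2 and SR kinase genes, 19 had a higher and 3 a lower mean in WT. The largest differences in SR protein genes, which encode splicing activators, were in an intron of SRSF7, retained at 0.568 ± 0.015 in WT against 0.379 ± 0.046 in mhM (chromosome 2, 38976488 to 38976671) and an intron of SRSF2 at 0.786 ± 0.026 against 0.640 ± 0.053 (chromosome 17, 74731957 to 74732236). Neither passed alone, with adjusted p = 0.63 and 0.86 over stable events.

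In all, 19 events of 18 genes were called without TGFβ, 11 higher in WT and 8 lower; 10 were at 0 or 1 in every library and all 19 had a library at 0. PSMC5 lost its call without any 1 of the 6 libraries (adjusted p from 0.058 to 0.082). It had no spread within either untreated group, so that loss does not show a single library standing apart. The PSMC5 call was also lost without the variance trend (0.0501) and without events at 0 or 1 in every library (0.074). With 1 entry per distinct set of values it was lost too (0.055). HNRNPM had 0.988 ± 0.0039 in WT and 0.979 ± 0.0036 in mhM (adjusted p = 1), and adjusted p was also 1 for ENAH, CD44, FGFR2 and CTNND1. Of the 15 lists, only SR proteins passed among stable events, the lowest adjusted p of the others being 0.675. In that list 15 of 78 events (19.2%) had unadjusted p under 0.05, against a random median of 4.76% (permutation p = 6e-04, adjusted p = 0.009). The adjusted p covers the 15 lists of this contrast alone, not the 6 contrasts tried. Without 1 library the share was as low as 10.3%, with p up to 0.086 without WT untreated replicate 2. The SR share was 15.4% in WT against mhM with TGFβ (adjusted p = 0.402), 11.5% in the interaction (0.612), 3.85% for TGFβ in mhM cells (0.99) and 17.9% for the averaged TGFβ contrast (0.159). Averaged per gene first, the mean retention of the 22 introns, of 9 genes, was 0.519 ± 0.016 in WT and 0.479 ± 0.010 in mhM, and with TGFβ it was 0.492 ± 0.016 and 0.481 ± 0.015. The untreated difference of these gene means was 0.0399, against 0.00285 in 2419 other stable introns of 1555 genes. Over introns, without averaging per gene, it was 0.0513 against 0.0037. Of the 9 genes 7 were higher in WT, with a median difference of 0.020. CLK4, SRSF7 and SRSF2 made up 93.8% of the sum, and the mean of the other 6 was 0.0037. The interaction of this mean did not pass (difference -0.0294, exact permutation p = 0.235).

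**Figure D3:**
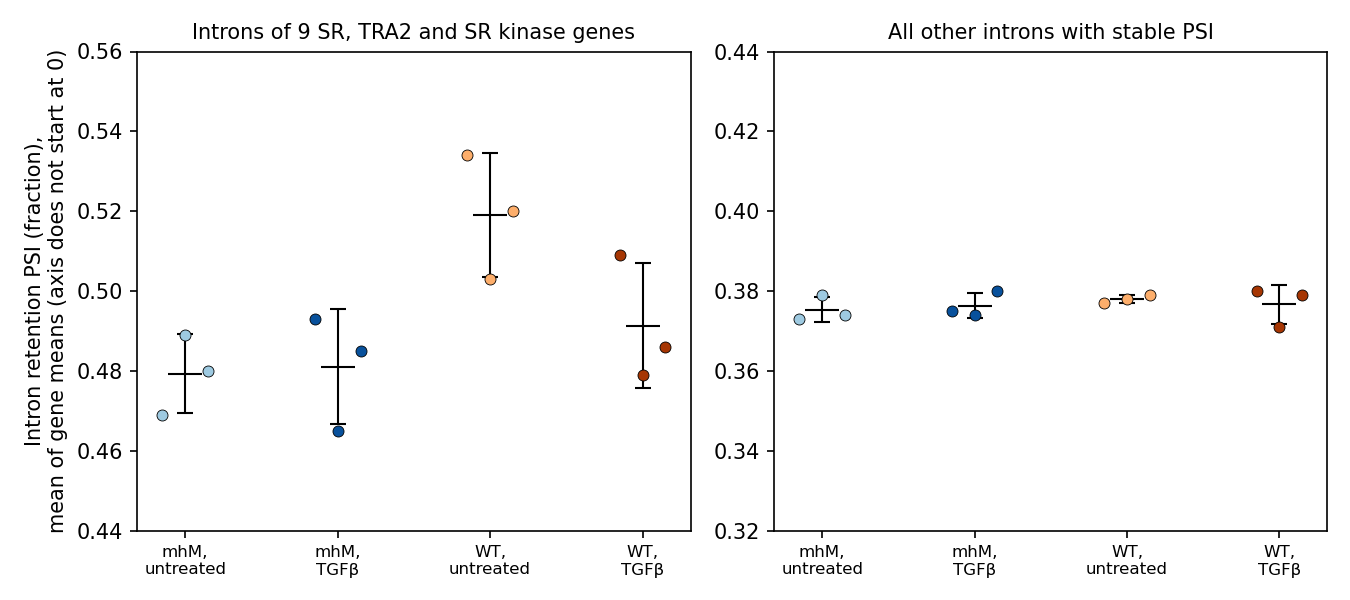
Intron retention PSI (fraction, vertical axes not starting at 0) per library, as the mean of gene means, for 22 introns of 9 SR, TRA2 and SR kinase genes (left) and 2419 other stable introns of 1555 genes (right), by group; dots are libraries and black bars the mean ± SD of 3. The means of the listed genes lie at 0.503 to 0.534 in WT untreated libraries and at 0.469 to 0.489 in mhM untreated libraries, and those of the other genes at 0.371 to 0.380 in all 12 libraries.

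With TGFβ, WT and mhM cells differed in keratin 15 and TP53I11, among others. The KRT15 first exon was at 1 in WT and 0 in mhM (adjusted p = 3e-04), and retention of an overlapping KRT15 stretch was 0.444 ± 0.026 in WT and 1 in mhM (chromosome 17, 39674713 to 39677937; adjusted p = 0.011). TP53I11 was at 1 in WT and 0 in mhM (adjusted p = 3.6e-08), and C2orf42 at 1 and 0.037 ± 0.064 (adjusted p = 0.015, but 0.078 with the logit of PSI). A 104-bp exon of TMEM161A was fully included in WT and at 0.891 ± 0.0073 in mhM (adjusted p = 0.0026), while first exons of ZADH2 and HERC3 were at 0 in WT and at 0.889 ± 0.19 and 0.166 ± 0.030 in mhM (adjusted p = 0.0095 and 0.0030). In all, 10 events of 6 genes were called, 7 higher in WT and 3 lower; 2 were at 0 or 1 in every library and 2 calls were made among events with no library at 0. TTC28-AS1, SCAPER and C22orf23 were next by p and not called, with differences of 0.04, -0.03 and -1. C22orf23 was called with a PSI range of at least 0.05 (adjusted p = 0.033). ENAH stood at 0.882 ± 0.013 in WT and 0.849 ± 0.0088 in mhM (adjusted p = 0.85). HNRNPM and CD44 had adjusted p = 1, CTNND1 0.99 and FGFR2 0.88.

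In each of these 5 contrasts, leaving out any 1 of the libraries compared raised the number of calls, to between 40 and 81, of which 12 to 38 had no spread within any group. With all libraries there were 10 to 19 calls per contrast, below the 32 called in the simulated WT contrast, where nothing was moved.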

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

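The test for libraries without reads, and the averaged TGFβ contrast with its splits, were chosen only after the results were seen; the others in this part were planned. Groups of 3 are too small for a test of single libraries that stand apart.

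Responses to TGFβ differed between the constructs in 14 events, by the limma interaction test. The first exon of KRT15, a basal keratin, had the largest difference of responses, 1.12 (adjusted p = 0.00052). Differences of 1 were found for first exons of PHF21B and SERGEF (2 events of SERGEF, both from position 17809960 on chromosome 11), the last exon of AC017099.3, the PSD exon, and the TP53I11 exon and 5' splice site (each adjusted p = 1.6e-07). Differences of -1 were found for 5' splice sites of APBB2 and CRB1 and the FAM166A intron (each adjusted p = 1.6e-07) and for the PRSS36 5' splice site (adjusted p = 1.7e-06). HERC3, a ubiquitin ligase gene, had -0.17 (adjusted p = 0.025), which was lost with a PSI range of at least 0.05 (adjusted p = 0.11) and without events at 0 or 1 in every library (0.088).

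Of these 14 events, 12 were at exactly 0 or 1 in every library. Among all 3501 varying events of that kind, 12 were constant within every group, against a median of 10 (1 to 28) over 15400 ways to part the libraries into 4 threes, and a share of 0.362 of these gave as many, so chance could not be excluded. In mutually exclusive exons, where PSI has no preferred direction and averages 0.485, 77.5% of the values in the 34 events of that kind were 0; 29 events were mostly 0 and 4 mostly 1 (87.9%, exact 95% interval 71.8% to 96.6%). That excess is consistent with libraries without junction reads being entered as 0. A switch set by construct and TGFβ in genes such as PRSS36 and PSD remains open, because these 12 events cannot be told apart from chance patterns and the read depth behind them is unknown.

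Splits of the same libraries, with the real grouping counted among them, were compared for each contrast. For TGFβ in mhM cells 17 events were called, 6 of the 10 splits gave as many and the highest other gave 27. For TGFβ in WT cells the values were 17, 5 of 10 and 29; for WT against mhM without TGFβ 19, 3 of 10 and 23; and with TGFβ 10, 10 of 10 and 27. In these contrasts 10 splits are too few for a share under 0.05. For the interaction 14 events were called, 85 of 100 splits gave as many and the highest other gave 33. For TGFβ averaged over constructs the values were 18, 56 of 100 and 33. In both, the splits other than the real grouping were drawn at random. Chance was not excluded for either count.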

How the results depend on the processing

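Alternatives with 1 entry per distinct set of values, stable events, no library at 0 and no events at 0 or 1 in every library were chosen after seeing the data. Counts of calls are given for TGFβ in mhM, TGFβ in WT, the interaction, WT against mhM untreated, WT against mhM with TGFβ, and averaged TGFβ, in that order; the values reported were 17, 17, 14, 19, 10 and 18. The logit of PSI gave 31, 41, 39, 35, 39 and 37 calls. Stable events gave 0, 3, 0, 0, 0 and 0 by limma, with 5.19%, 7.32%, 5.21%, 5.04%, 7% and 7.20% of events at unadjusted p under 0.05. Events with no library at 0 gave 1, 1, 0, 2, 2 and 0, with 4.94%, 6.17%, 4.43%, 4.83%, 5.90% and 5.92%. Without events at 0 or 1 in every library there were 7, 10, 1, 2, 8 and 4, and with 1 entry per distinct set of values 9, 14, 6, 8, 9 and 9; both sets hold fewer events by construction. Fits on only the groups compared, not possible for the interaction, gave 66, 76, 75 and 74 calls. With no minimum difference TGFβ in WT gave 27. A limit of 0.2, no variance trend and a PSI range of at least 0.05 kept each count within 1.5 times, and settings for missing values changed nothing because no value was missing. Leaving out 1 library gave 55 to 80, 46 to 81, 40 to 66, 47 to 74, 47 to 70 and 35 to 63 calls. Except where construction shows it, the cause was not tested.

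Replicate numbers did not pair the libraries: over 12 pairs the correlation of same-numbered deviations from the group means ran from -0.014 to 0.019. With the replicate block there were 11, 5, 13, 10, 5 and 14 calls.

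Under the size rule, a limit of 0.2 gave 7544 responsive events in mhM, with 56.7% forward and 59.0% reverse. Stable events gave 904, 89.5% and 92.2%, and events with no library at 0 gave 4405, 63.1% and 67.4%. With 1 entry per distinct set of values the forward share was 43.3%. Without 1 library the forward share ran from 42.2% to 47.7% and the reverse share from 45.2% to 51.8%. The forward share lay below the reverse share in each of these event sets and with this limit, but above it without any 1 of the 6 mhM libraries. That turn follows the count of responsive events in mhM cells, which rose to at least 14872 without 1 mhM library. The left-out share of 48.8% was 71.1% in stable events and 50.2% with no library at 0. In WT pairs the same chosen events gave 67.6% and 49.3%.

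The direction turned only for events that were not called. The CTNND1 exon, WT against mhM with TGFβ, was -0.001 without WT TGFβ replicate 1. The ENAH exon with TGFβ in WT was 0.007 without WT untreated replicate 1 and 0.004 without WT TGFβ replicate 2. WT against mhM untreated, ENAH was -0.009 without WT untreated replicate 1 and -0.001 without mhM untreated replicate 1. Of 133 named results, 122 kept their side of the threshold with the logit, 113 with the block and 128 without the variance trend. Of the event types, 2 passed for TGFβ in mhM, and 1 against only events with a library at 0, a background chosen after seeing the data. HNRNPH3 (adjusted p = 0.036) and TGIF1 (0.029) were called in WT only with the logit. The depth behind each fraction is unknown, so no limit from depth can be given, and the test of sequence around exons was not run.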

Other observations

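The averaged TGFβ contrast, all events named in this part, the tests of selection and of a lower response in WT, and the tests of unspliced RNA and of the construct's action on introns were chosen only after the results were seen. The test of a single library was planned.

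In the contrast averaged over both constructs, the 33-bp exon of CA12 was lower with TGFβ by limma over all events (difference -0.112, adjusted p = 0.0047), but did not pass over stable events (adjusted p = 0.082), with the logit of PSI (0.087), with a PSI range of at least 0.05 (0.0521) or among events with no library at 0 (0.23). The other events named next had differences of the same sign in both constructs, as had 52.7% of all stable events, and passed neither over all nor over stable events; their adjusted p is over stable events. A 57-bp exon of CLSTN1 differed by 0.124 (adjusted p = 0.23; mhM 0.292 ± 0.010 and 0.471 ± 0.040, WT 0.378 ± 0.024 and 0.448 ± 0.0033) and the TPM1 first exon by -0.132 (adjusted p = 0.23). A 240-bp exon of TJP1, which encodes the tight junction protein ZO-1, was at 0.525 ± 0.026 and 0.380 ± 0.046 in mhM and at 0.485 ± 0.020 and 0.413 ± 0.012 in WT (adjusted p = 0.40). A 39-bp exon of MYO6, a myosin, was at 0.155 ± 0.016 and 0.0731 ± 0.0079 in mhM and at 0.143 ± 0.021 and 0.110 ± 0.0076 in WT (adjusted p = 0.40). The actin list did not pass among stable events in this contrast (12.9% of its events at unadjusted p under 0.05, permutation p = 0.0324, adjusted p = 0.162). By limma 0 stable events were called in this contrast, 7.20% had unadjusted p under 0.05, and 18 events were called over all events.

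Single introns of 2 RNA-binding protein genes outside the SR list also read higher in WT untreated libraries than in the other groups. An intron of PNISR, an SR-related gene, was retained at 0.427 ± 0.029 there, against 0.252 ± 0.013 in mhM untreated, 0.215 ± 0.026 in mhM with TGFβ and 0.212 ± 0.034 in WT with TGFβ (chromosome 6, 99851758 to 99852479). Its difference with TGFβ in WT cells passed among stable events (adjusted p = 0.043) but not over all events (adjusted p = 0.090), while its difference between untreated constructs (adjusted p = 0.43) and its interaction (adjusted p = 0.94) did not pass. An intron of CIRBP, a cold-inducible RNA-binding protein, was at 0.161 ± 0.014 in WT untreated, 0.0773 ± 0.0065 in mhM untreated, 0.0641 ± 0.0056 in mhM with TGFβ and 0.0757 ± 0.00081 in WT with TGFβ (untreated difference 0.084, adjusted p = 0.43 over stable and 0.0097 over all events, where it was not called because it lay under 0.1). An intron of CLK4, an SR protein kinase on the list, was at 0.272 ± 0.053, 0.0779 ± 0.088, 0.0842 ± 0.054 and 0.0790 ± 0.0044 in the same order (untreated difference, adjusted p = 0.61). The shared first-exon junctions of C22orf29 and GNB1L were at 0 without and 0.229 ± 0.049 with TGFβ in WT cells, which passed among stable events (adjusted p = 0.043; interaction adjusted p = 0.082) but not over all events (adjusted p = 0.055).

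The higher mean of the listed SR, TRA2 and SR kinase introns in WT untreated libraries, averaged per gene and carried by CLK4, SRSF7 and SRSF2, was noticed and weighed in the same libraries against technical explanations. More unspliced RNA throughout these libraries stays open. The untreated difference of the other stable introns was a ratio of 0.0714 of the listed one. However, the 6 listed genes without those 3 differed by only 0.0037, against 0.00285 in the others. Of 140 stable introns with unadjusted p under 0.05, 97 were higher in WT. That tilt was not particular to introns: 342 of 547 such skipped exons were higher too, though only 57 of 114 such 5' splice sites. A single library is argued against: at least a ratio of 0.81 of the difference was left without any 1 WT untreated library. A candidate explanation is that the construct acts on these introns without TGFβ. The interaction (exact permutation p = 0.235) asks whether the construct difference changes with TGFβ, so it cannot decide this. WT untreated libraries lay at 0.503 to 0.534 and mhM untreated libraries at 0.469 to 0.489, but this is the pattern that was noticed. With 3 libraries per group whose cultures are not stated, the explanation stays open.

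The share of mhM-responsive events that were under 0.1 in WT, among them exons of MAP3K7, TPM1 and TJP1, was weighed in the same way. Events selected on 4 mhM libraries fell under 0.1 in the left-out mhM pair about as often as in WT pairs, with a difference of -0.1 percentage points, and simulated libraries with no effect gave 47.0%. This is consistent with the share coming largely from the selection of noisy differences on 1 construct. A lower response in WT cells was not shown. The exact permutation test (p = 0.14) compares in effect how many events responded in each construct. It does not ask whether the same events responded less in WT cells, so it cannot decide this. Smaller effects on single exons remain open. The forward share lay below the reverse share in all libraries and above it without any 1 mhM library. That order follows the number of responsive events per construct, which rose when a library of that construct was left out, so its turn decides nothing here.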
